A study of Mus musculus with 36 samples.

How the data were processed

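RNA-seq libraries of total RNA were made with the KAPA stranded kit from mouse bone marrow haematopoietic stem and progenitor cells, control or with conditional knockout of Taf1, per the labels' protocols. All cytokines were used at 50 ng/ml in medium with horse serum. The labels do not state how the deletion was induced, which part of Taf1 it removes, or whether the replicates of a group came from separate mice. The values are TPM per gene as the authors deposited them, in 2 tables of 24411 genes, and the 12 columns of the day 0 and day 3 libraries were equal in both. Per the submitters' processing notes, the tools were RSEM, whose version is not given in the sources used here, and DESeq2 1.38.3, with the mm10 build. TPM keeps no depth, so the number of reads behind a value is unknown and no counting interval is given. The annotation behind the gene symbols is not given in the sources used here, and coordinates were taken from GENCODE M21 on the same build. The mitochondrially encoded genes were not among the symbols of the tables and were not analysed here, and 17 of 942 list symbols had no match. TPM sums to a fixed total in each library, so a gene group that takes a larger share lowers all others. Rpph1 and Rmrp, short structural RNAs, took 2.29% to 16.1% of the TPM, histone genes 3.35% to 17% and S100a8 with S100a9 0.109% to 23.4%.

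Samples were grouped by genotype, day and course from the labels into 12 groups of 3 libraries. Values were analysed as log2(TPM + 1), a pseudocount of 1 TPM, so folds are on that scale and understate the change of genes with low TPM. Genes with at least 1 TPM in at least 3 libraries were kept, 11953 in the macrophage course, 11905 in the granulocyte course and 11269 among the day 7 libraries. Linear models were fitted with limma 3.58.1 in R 4.3.3 with 1 coefficient per group and a moderated variance with trend, over the 24 libraries of a course, or the day 7 libraries of both courses, and p-values were adjusted by Benjamini and Hochberg with a threshold of 0.05. There were 17 comparisons: knockout against control at 6 stages, its average in each course, day 7 against day 0 per genotype and course, the interaction of genotype and day in each course, day 3 against day 0 over both genotypes, and the lineages at day 7 in controls and as a difference of knockout effects. The 2 interactions share their day 0 libraries and were not compared with each other. A total of 43 gene lists were fixed before the data were examined, together with the grouping, the tests, the alternatives and the rule for named genes, and lists with at least 5 tested members were tested with limma's camera with a preset correlation of 0.01. Of 485 list tests over 12 planned contrasts 230 passed with camera and 278 with fry, which asks whether a list's genes move one way on balance. With a correlation estimated from the residuals 0 passed, 42 had an unadjusted p under the threshold, and the lowest adjusted p was 0.0916, or 0.0846 over all 17 comparisons.

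Named genes were chosen by rule: Taf1 and other TFIID subunits past the threshold, per comparison the 10 largest rises and falls (6 for time and lineage) among passing genes with at least 5 TPM in the higher group and libraries that did not overlap, up to 4 members per list with the smallest p, 10 fixed genes in each knockout comparison, and sex-linked genes as a label check. The alternatives were pseudocounts of 0.1 and 5 TPM, no filter on low values, a filter of 5 TPM, median-of-ratios scaling, the groups of the contrast fitted alone, the replicate number as a block, day 3 as the start, a choice of activated genes on controls alone, and each library left out in turn. After the data were seen, leaving out short structural RNA and histone genes, subtracting the median of all genes, and leaving out knockout replicates 2 and 3 at day 7 were added. Median-of-ratios scaling used factors from 0.8192 to 1.159. Where it moved the median of all genes by more than 0.1 log2, list counts after scaling are given beside those from TPM as deposited. Of 287 gene results named or examined, apart from Taf1 at the 6 stages, 286 kept direction and side of the threshold under it.

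Replicate numbers were checked as pairs by the correlation of deviations from the group means. Between knockout and control the numbers paired the samples at day 5 of the macrophage course (0.3, 0.182 and 0.267) but not at the other stages, where the lowest was -0.248 at day 0, 0.00417 at day 3, 0.0621 at day 5 granulocyte, -0.288 at day 7 macrophage and -0.0914 at day 7 granulocyte. Between the lineages of the same genotype and day, divided from common cultures by the protocol, the correlation of equal numbers was at least 0.231. Other numbers reached 0.614 at day 5 and 0.43 at day 7 in controls, so that a number marks a shared culture is an inference. The scripts were tested on simulated data with known changes. A log2 change of 1 was recovered for 91.2% to 97.5% of changed genes in the 6 knockout comparisons, on 11953 or 11905 genes, and for 81.2% and 75% in the interactions of the macrophage and granulocyte courses. A change of 0.5 was recovered for 45% to 58.8%, 15% and 7.5%, and 1.21% to 7.23% of calls were false.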

Results

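Expression was measured by RNA-seq of total RNA in mouse bone marrow haematopoietic stem and progenitor cells from controls or with conditional knockout of Taf1, differentiated in culture. Taf1 is the largest subunit of TFIID, the general transcription factor that recognises core promoters for RNA polymerase II. Cells were sampled at day 0, after 3 days with SCF and IL-3, and at days 5 and 7 of either a macrophage course (GM-CSF with M-CSF, then M-CSF alone) or a granulocyte course (SCF, IL-3 and G-CSF, then G-CSF alone). The 36 libraries formed 12 groups of 3, and the day 0 and day 3 libraries served both courses. The time series was made to follow the activation of genes of differentiation in knockout cells. Between 10289 and 11226 genes reached 1 TPM, the deposited measure of transcript abundance, in a library. The number of reads behind a TPM value is unknown here, and Pearson's r across genes between replicates lay between 0.973 and 0.997. Values below are means ± SD over n = 3 libraries in TPM, log2 changes carry their SE, and p-values measure only the spread between these libraries, since the labels do not say that they came from separate mice.

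Taf1 itself (chromosome X, 101532734 to 101601789, plus strand, mm10) was lower in every knockout library than in every control library at each stage except day 3. At day 0 it fell by 0.61 ± 0.08 on the log2 scale, from 14.1 ± 0.491 TPM in controls to 8.85 ± 0.303 TPM (limma adjusted p = 1.13e-05). At day 5 the level was 13.1 ± 0.622 against 6.11 ± 0.15 TPM in the macrophage course and 14.2 ± 1.87 against 7.36 ± 0.153 TPM in the granulocyte course, log2 changes of -0.99 and -0.85 (limma adjusted p = 1.87e-08 and 3.67e-06). At day 7 it was 13.2 ± 0.35 against 7.19 ± 0.407 TPM and 11.2 ± 0.92 against 7.77 ± 1.03 TPM, log2 changes of -0.80 and -0.47 (limma adjusted p = 2.86e-07 and 0.0012). At day 3 the 3 control libraries held 9.62, 10.9 and 11.45 TPM and the 3 knockout libraries 8.66, 10.29 and 9.06 TPM, a log2 value of -0.17 that did not pass (limma adjusted p = 0.0711). That day 3 value passed after median-of-ratios scaling (-0.21, adjusted p = 0.00748), with short structural RNA and histone genes left out (-0.20, adjusted p = 0.0301), without control replicate 1 (-0.24, adjusted p = 0.0207) and without knockout replicate 2 (adjusted p = 0.0276). Which part of Taf1 was deleted is not given in the sources used here, so reads from outside that part may enter these values, and incomplete deletion was not tested. Xist lay between 3.58 and 32.01 TPM, and Ddx3y, Eif2s3y, Kdm5d and Uty were listed at 0 in all 36 libraries.

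**Figure D1:**
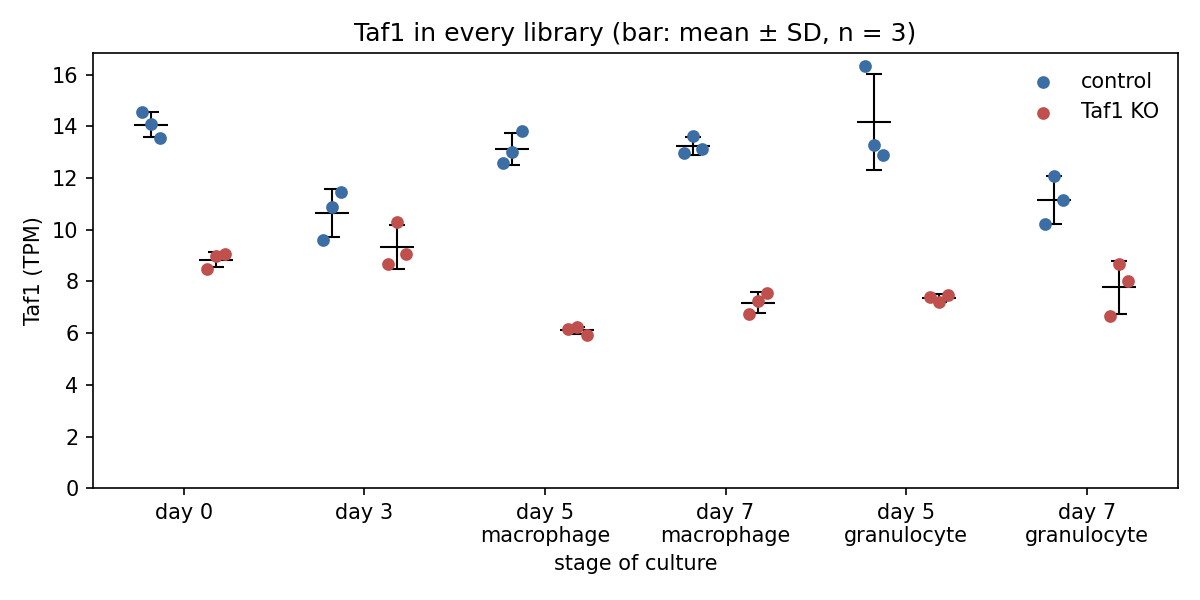
Taf1 level in TPM (y axis) at the 6 stages (x axis) in control and knockout cells, with 1 point per library and the mean ± SD of n = 3. Controls lay between 9.62 and 16.32 TPM and knockout libraries between 5.94 and 10.29 TPM, and the groups overlapped at day 3 alone.

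Averaged over the 4 time points of each course, most other TFIID subunits were higher in the knockout, where Taf1 was lower. Taf13 rose by log2 1.28 ± 0.07 in the macrophage course and 1.2 ± 0.07 in the granulocyte course (limma adjusted p = 1e-11 and 2.59e-11), and Taf12, which forms a histone-fold pair with Taf4, rose by 1.08 ± 0.05 and 1.01 ± 0.05. Taf6 rose by 0.76 ± 0.06 and 0.76 ± 0.05, Taf5 by 0.65 ± 0.06 and 0.69 ± 0.08, whereas Taf8 fell by 0.49 ± 0.05 and 0.32 ± 0.07 (limma adjusted p = 2.05e-07 and 0.000811). Of the 15 subunits tested, 12 rose and 2 fell in the macrophage course and 13 rose and 2 fell in the granulocyte course, the same numbers adjusted over the list alone (camera adjusted p = 0.000491 and 0.000566, adjusted p = 0.596 and 0.727 with an estimated correlation). Hexim1, an inhibitor of the elongation kinase P-TEFb, rose by 1.09 ± 0.05 and 1.15 ± 0.05, Mknk2, a kinase that phosphorylates eIF4E, by 1.04 ± 0.06 and 1.09 ± 0.07, and Kank3 by 1.45 ± 0.06 and 1.44 ± 0.06. Among the falls were Selm, a selenoprotein gene (-2.11 ± 0.07 and -1.92 ± 0.09), and Cercam (-2.09 ± 0.09 and -1.92 ± 0.10). Lmo1, a LIM-domain transcriptional cofactor, fell by 2.39 ± 0.11 in the granulocyte course, where the interferon-induced Usp18 rose by 1.29 ± 0.12. In the macrophage course Rpl26, a ribosomal protein gene, rose by 1.27 ± 0.10 and the p53 target Ccng1 by 0.77 ± 0.06. The average knockout effect passed for 7209 genes in the macrophage course (3336 higher and 3873 lower) and 7030 in the granulocyte course (3928 higher and 3102 lower), at the adjusted p threshold of 0.05. After median-of-ratios scaling the granulocyte split was 3604 higher and 4031 lower.

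At day 0, before lineage cytokines, knockout cells held more calprotectin, chitinase-like and interferon-induced transcripts and fewer erythroid, eosinophil and class II transcripts. S100a8 and S100a9, which encode the calprotectin subunits, rose by log2 2.95 ± 0.46 (1943 ± 1130 to 13850 ± 4970 TPM) and 3.02 ± 0.51 (965 ± 679 to 7064 ± 3700 TPM). These genes lie close together on chromosome 3, at 90668978 to 90670035 on the plus strand and 90692632 to 90695721 on the minus strand (mm10). Chil3, a chitinase-like protein of myeloid cells, rose by 4.67 ± 0.55 and Lcn2, an iron-siderophore-binding granule protein, by 2.68 ± 0.45 (limma adjusted p = 3.44e-06 and 0.000212). In the interferon response list 27 of 37 tested members rose and 10 did not pass (29 rose adjusted over the list alone), with a median log2 of 0.74 (camera adjusted p = 2.68e-14, adjusted p = 0.348 with an estimated correlation). Oas1a rose by 1.87 ± 0.14, Isg15, a ubiquitin-like modifier, by 1.97 ± 0.22, and Irf7, a transcription factor of the interferon pathway, by 1.67 ± 0.18. Reads of Oas1a can be shared with its near-identical neighbours. Of 25 p53 targets, 13 rose and 12 did not pass (14 rose and 1 fell adjusted over the list alone), with a median of 0.39 (camera adjusted p = 0.000166, adjusted p = 0.459 with an estimated correlation). The cell cycle inhibitor Cdkn1a rose by 1.95 ± 0.18, from 1.70 ± 0.436 to 9.36 ± 0.116 TPM, Ccng1 by 1.0 ± 0.13 and the proapoptotic Pmaip1 by 1.56 ± 0.21.

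Some other lineage genes and most cytosolic ribosomal protein genes fell at day 0. Class II antigen presentation had 9 of 10 members lower, 9 also adjusted over the list alone, with a median of -1.16 (camera adjusted p = 1.38e-09, adjusted p = 0.348 with an estimated correlation). H2-Aa, a class II chain, fell from 74.2 ± 37.3 to 7.23 ± 6.0 TPM and the invariant chain Cd74 from 90.5 ± 46.2 to 12.1 ± 10.7 TPM (limma adjusted p = 1.3e-05 and 5.46e-05). Of 12 dendritic cell genes 6 fell, 6 also adjusted over the list alone (camera adjusted p = 4.87e-05, adjusted p = 0.439 with an estimated correlation). Erythroid genes fell in 13 of 19 cases, 13 adjusted over the list alone, with a median of -0.71 (camera adjusted p = 5.91e-08, adjusted p = 0.439 with an estimated correlation). They included Ermap (-0.80 ± 0.12). Eosinophil genes fell in 6 of 9 cases (7 adjusted over the list alone), among them the peroxidase Epx at -2.60 ± 0.50 (camera adjusted p = 8.31e-05, adjusted p = 0.439 with an estimated correlation). The mast cell and basophil list had 5 of 15 lower (6 adjusted over the list alone), with the basophil protease Mcpt8 at -2.68 ± 0.53 (camera adjusted p = 0.00378, adjusted p = 0.781 with an estimated correlation). Cytosolic ribosomal protein genes fell in 47 of 65 cases and rose in 1 (52 and 1 adjusted over the list alone), with a median of -0.39 (camera adjusted p = 1.09e-23, adjusted p = 0.459 with an estimated correlation). Rplp1 and Rps21 fell by 1.03 ± 0.11 and 1.05 ± 0.10. Prss50, a serine protease gene, fell by 2.82 ± 0.16, and Gtf2b, the general factor TFIIB, rose by 0.63 ± 0.09. The fixed genes Mpo, Kit and Cd34 did not pass: Mpo 0.07 ± 0.43, Kit -0.06 ± 0.18 and Cd34 0.21 ± 0.17 (limma adjusted p = 0.945, 0.868 and 0.413). The sign of Mpo turned after rescaling (-0.01), without control replicate 2 (-0.075) and without knockout replicate 2 (-0.01), and that of Kit turned without control replicate 1 (0.02). In all 2790 genes passed, 1568 higher and 1222 lower, and the split was 1305 higher and 1760 lower after median-of-ratios scaling but 2508 and 1278 with short structural RNA and histone genes left out. S100a8 and S100a9 held 0.291% of the TPM in controls and 2.09% in knockout cells.

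At day 3, with SCF and IL-3, knockout cells held less macrophage and platelet-lineage RNA and more RNA of nucleolar, S phase, cholesterol synthesis and respiratory genes. Of 29 macrophage genes 22 fell and 7 did not pass (22 adjusted over the list alone), with a median log2 of -1.53 (camera adjusted p = 1.09e-09, adjusted p = 0.421 with an estimated correlation). Adgre1, which encodes the F4/80 antigen, went from 103 ± 15.2 to 22.1 ± 4.58 TPM (-2.18 ± 0.15), and the scavenger receptor Msr1 from 20.0 ± 1.77 to 1.86 ± 0.423 TPM. Csf1r, the M-CSF receptor, fell by 1.23 ± 0.11, the fatty acid carrier Fabp4 by 3.52 ± 0.26 and Apoe by 3.50 ± 0.48 (limma adjusted p = 3.63e-08, 3.28e-09 and 4.88e-06). Lysosome genes fell in 18 of 30 cases and rose in 1, counts that were the same adjusted over the list alone (camera adjusted p = 5.03e-05, adjusted p = 0.597 with an estimated correlation). The protease Ctsl was at log2 -2.70 ± 0.21. All 17 megakaryocyte genes tested fell, 17 also adjusted over the list alone, with a median of -1.90 (camera adjusted p = 7.78e-09, adjusted p = 0.541 with an estimated correlation). The platelet chemokine Ppbp went from 529 ± 160 to 37.7 ± 33.7 TPM, the collagen receptor Gp6 from 11.1 ± 2.42 to 1.01 ± 0.659 TPM, Clec1b fell by 3.51 ± 0.37 and Vwf by 2.37 ± 0.28. Mt2, a metallothionein, fell by 3.86 ± 0.60.

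The lists that rose at day 3 included those of replication, nucleoli, sterols and respiration. In the Myc and nucleolar list 24 of 29 members rose and 1 fell (25 and 1 adjusted over the list alone), with a median of 0.80 (camera adjusted p = 3.33e-09, adjusted p = 0.541 with an estimated correlation). Cad, which starts pyrimidine synthesis, rose by 1.78 ± 0.13 and Bop1, a ribosome biogenesis factor, by 1.75 ± 0.15. S phase genes rose in 27 of 32 cases and fell in 2, the same adjusted over the list alone (camera adjusted p = 1.07e-08, adjusted p = 0.558 with an estimated correlation), including the flap endonuclease Fen1 (1.76 ± 0.19) and the helicase subunit Mcm2 (0.83 ± 0.10). Cholesterol synthesis genes rose in 20 of 21 cases, 20 adjusted over the list alone, with a median of 1.15 (camera adjusted p = 4.28e-07, adjusted p = 0.573 with an estimated correlation). Insig1 rose by 1.94 ± 0.23 and Hmgcs1 by 1.28 ± 0.17. Oxidative phosphorylation genes rose in 29 of 39 cases (31 adjusted over the list alone, camera adjusted p = 7.78e-09, adjusted p = 0.558 with an estimated correlation). The complex I subunit Ndufb10 was at log2 1.05 ± 0.10. RNA polymerase II subunits rose in 10 of 12 cases, 10 adjusted over the list alone (camera adjusted p = 1.26e-05, adjusted p = 0.541 with an estimated correlation), among them Polr2l (1.47 ± 0.11) and Polr2f (1.21 ± 0.10). TFIID subunits rose in 12 of 15 cases and 1 fell (12 and 2 adjusted over the list alone, camera adjusted p = 0.000224, adjusted p = 0.541 with an estimated correlation). Cytosolic ribosomal protein genes fell in 43 of 65 cases and rose in 2 (45 and 2 adjusted over the list alone, camera adjusted p = 1.2e-07, adjusted p = 0.626 with an estimated correlation). Rpsa fell by 1.02 ± 0.10, whereas Rpl26 rose by 2.15 ± 0.19. Ccl17, a ligand of the receptor Ccr4, rose by 2.59 ± 0.36. Stfa2, a cystatin of a family with near-identical members and therefore uncertain, rose by 3.19 ± 0.47. In all 6355 genes passed, 3167 higher and 3188 lower (limma).

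At day 5 of the macrophage course, many macrophage and lysosome genes were lower in the knockout, and some dendritic cell and interferon genes were higher. Of 29 macrophage genes 23 fell and 1 rose (24 and 1 adjusted over the list alone), with a median log2 of -1.09 (camera adjusted p = 0.000726, adjusted p = 0.85 with an estimated correlation). Adgre1 went from 146 ± 21 to 45.3 ± 1.12 TPM (-1.66 ± 0.15), Fabp4 from 118 ± 49.2 to 19.2 ± 5.83 TPM, and the scavenger receptor Marco from 3.57 ± 1.12 to 0.15 ± 0.0866 TPM. Lysosome genes fell in 21 of 30 cases (22 adjusted over the list alone, camera adjusted p = 0.0126, adjusted p = 0.85 with an estimated correlation). The acid lipase Lipa was at log2 -0.98 ± 0.15 and the glucosidase Gaa at -1.13 ± 0.13. Camp, the cathelicidin of neutrophil granules, went from 1549 ± 830 to 117 ± 47.3 TPM. The protease Asprv1 fell by 4.17 ± 0.35, the cytotoxic granule gene Nkg7 by 3.76 ± 0.44, and the coagulation factor genes F13a1 and F7 by 3.32 ± 0.58 and 3.18 ± 0.27 (limma adjusted p = 0.000165 and 3.37e-08). Dendritic cell genes rose in 6 of 12 cases and 1 fell (7 and 1 adjusted over the list alone, camera adjusted p = 2.59e-05, adjusted p = 0.85 with an estimated correlation). The chemokine Ccl22 rose by 1.82 ± 0.25, and Cd209a, a lectin listed at 0 in the controls, stood at 1.44 ± 0.521 TPM in the knockout. Interferon genes rose in 11 of 37 cases and fell in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 3.01e-08, adjusted p = 0.85 with an estimated correlation). Irf7 was at log2 1.43 ± 0.18 and Oas1a at 0.98 ± 0.14. The proteoglycan Sdc4 rose by 1.79 ± 0.16 and Cd34 by 0.99 ± 0.17.

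In all 5143 genes passed at day 5 of the macrophage course, 611 higher and 4532 lower. After median-of-ratios scaling 2237 were higher and 2359 lower, and the median log2 of all genes went from -0.228 to -0.0155. After rescaling the macrophage list had 17 members lower and 3 higher, lysosome 11 lower, interferon 16 higher and 1 lower, and dendritic 7 higher. Oxidative phosphorylation genes, 4 higher and 4 lower of 39 as deposited (3 and 3 adjusted over the list alone, camera adjusted p = 2e-04, adjusted p = 0.85 with an estimated correlation), were 24 higher after rescaling, with Ndufb10 at 0.66 ± 0.10 before and 0.92 after. Cytosolic ribosomal protein genes fell in 54 of 65 cases and rose in 1 (56 and 1 adjusted over the list alone, camera adjusted p = 3.01e-08, adjusted p = 0.85 with an estimated correlation), and in 33 after rescaling. Rpsa fell by 1.27 ± 0.10 and Rps21 by 0.97 ± 0.10. S100a8 and S100a9 held 21.5 ± 3.23% of the TPM in the knockout and 11.2 ± 5.44% in controls, where replicate 1 stood apart at 4.93%. S100a8 rose by 1.3 ± 0.46 (limma adjusted p = 0.0272), a call lost without control replicate 1 (0.64, adjusted p = 0.208), knockout replicate 2 (adjusted p = 0.0723) or knockout replicate 3 (adjusted p = 0.071). It was also lost with no filter on low values (adjusted p = 0.0873) and with the groups of the contrast fitted alone (adjusted p = 0.23). Cdkn1a rose by 0.60 ± 0.18 (limma adjusted p = 0.0106), but without control replicate 2 it stood at 0.39 (adjusted p = 0.0768) and with these groups fitted alone the adjusted p was 0.0695.

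At day 5 of the granulocyte course most macrophage, lysosome and eosinophil genes were lower in the knockout and some progenitor genes were higher. Macrophage genes fell in 26 of 29 cases (29 adjusted over the list alone), with a median log2 of -1.48 (camera adjusted p = 3.39e-14, adjusted p = 0.303 with an estimated correlation). Msr1 went from 49.5 ± 3.42 to 4.80 ± 1.07 TPM, Marco from 4.67 ± 0.246 to 0.12 ± 0.115 TPM, and Gpnmb, a glycoprotein of macrophages, from 570 ± 62.8 to 145 ± 6.79 TPM. Lysosome genes fell in 24 of 30 cases (26 adjusted over the list alone, camera adjusted p = 2.6e-08, adjusted p = 0.849 with an estimated correlation). The protease Ctsd was at log2 -1.41 ± 0.15 and Lipa at -1.40 ± 0.15. In the oxidase and phagocytosis list 11 of 20 members fell (15 adjusted over the list alone, camera adjusted p = 0.00469, adjusted p = 0.849 with an estimated correlation), including the Fc receptor Fcgr1 (-1.98 ± 0.29) and Tlr2 (-1.15 ± 0.15). The lectin receptor genes Clec4d and Clec4e fell by 2.37 ± 0.25 and 1.70 ± 0.16. Eosinophil genes fell in 7 of 8 cases, 7 adjusted over the list alone (camera adjusted p = 0.00469, adjusted p = 0.849 with an estimated correlation). Epx was at log2 -2.66 ± 0.49 and Ear1, from a family with near-identical copies and therefore uncertain, at -3.81 ± 0.63. Mature neutrophil genes went both ways, 2 higher and 9 lower of 19, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.104, adjusted p = 0.849 with an estimated correlation). Camp fell from 919 ± 521 to 68.8 ± 19.1 TPM, the acute phase gene Saa3 from 77.9 ± 6.47 to 7.04 ± 1.1 TPM, F13a1 by 3.53 ± 0.35 and Asprv1 by 4.2 ± 0.41.

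Progenitor genes rose in 9 of 26 cases at day 5 of the granulocyte course and 2 fell, the same adjusted over the list alone (camera adjusted p = 0.00225, adjusted p = 0.849 with an estimated correlation). Cd34 went from 33.0 ± 0.678 to 95.3 ± 9.98 TPM, Meis1, a stem cell transcription factor, from 5.54 ± 1.21 to 14.9 ± 1.44 TPM, and the receptor Flt3 from 1.85 ± 0.382 to 4.50 ± 0.485 TPM. Myc rose by 0.79 ± 0.12. Among cytokines, Ccl17 rose by 3.27 ± 0.43, Ccl22 by 2.62 ± 0.52, Il4 by 2.44 ± 0.38 and Il13 by 3.01 ± 0.30, whereas the mast cell protease Mcpt4 fell by 2.81 ± 0.40 (limma adjusted p = 1.82e-05). Cytosolic ribosomal protein genes fell in 49 of 65 cases and rose in 1 (55 and 1 adjusted over the list alone, camera adjusted p = 4.39e-12, adjusted p = 0.849 with an estimated correlation). In all 3806 genes passed, 1095 higher and 2711 lower, or 2132 higher and 2648 lower after median-of-ratios scaling, and 2493 passed with these groups fitted alone. S100a8 rose by 1.11 ± 0.42 (limma adjusted p = 0.0497). That call was lost without control replicate 1 (0.48, adjusted p = 0.342) or any of knockout replicates 1, 2 and 3 (adjusted p = 0.0739, 0.112 and 0.114). A pseudocount of 5 TPM, no filter on low values, the groups fitted alone and the replicate block gave adjusted p = 0.0532, 0.155, 0.216 and 0.054.

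At day 7 of the macrophage course, interferon genes, p53 targets and lysosome genes were higher in the knockout, and mitotic, histone, granule and glycolytic genes were lower. Interferon genes rose in 33 of 37 cases (35 adjusted over the list alone), with a median log2 of 1.10 (camera adjusted p = 8.85e-18, adjusted p = 0.518 with an estimated correlation). The antiviral genes Ifit3, Ifit1 and Rsad2 went from 1.13 ± 0.254 to 20.6 ± 7.87 TPM, from 0.69 ± 0.121 to 13.4 ± 6.12 TPM and from 1.39 ± 0.206 to 26.8 ± 11.4 TPM, and Irf7 rose by 2.81 ± 0.18. Of 25 p53 targets 18 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 5.84e-05, adjusted p = 0.626 with an estimated correlation). Ccng1 was at log2 1.23 ± 0.13, Cdkn1a at 1.34 ± 0.18 and Mdm2, which targets p53 for degradation, at 1.02 ± 0.16. Lysosome genes rose in 17 of 30 cases, 17 adjusted over the list alone (camera adjusted p = 0.00355, adjusted p = 0.77 with an estimated correlation). The cathepsin genes Ctsl and Ctsb rose by 1.21 ± 0.21 and 1.0 ± 0.17. Mitotic genes fell in 25 of 32 cases (27 adjusted over the list alone, camera adjusted p = 8.52e-13, adjusted p = 0.626 with an estimated correlation), among them Ube2c (-0.95 ± 0.15) and Cenpa (-0.64 ± 0.11). Replication-dependent histone genes, near-identical copies and therefore uncertain, fell in 18 of 22 cases (19 adjusted over the list alone, camera adjusted p = 1.1e-10, adjusted p = 0.626 with an estimated correlation). Hist1h4b was at log2 -0.88 ± 0.13. Secondary and tertiary granule genes fell in 14 of 16 cases and rose in 1, the same adjusted over the list alone (camera adjusted p = 1.55e-07, adjusted p = 0.626 with an estimated correlation). Camp went from 1468 ± 864 to 34.1 ± 37.9 TPM, and the neutrophil antigen Cd177 and the ficolin Fcnb fell by 2.97 ± 0.53 and 2.90 ± 0.64. Glycolytic genes fell in 11 of 18 cases (15 adjusted over the list alone, camera adjusted p = 1.9e-07, adjusted p = 0.686 with an estimated correlation). Eno1 was at log2 -0.94 ± 0.18 and the lactate exporter Slc16a3 at -1.97 ± 0.47.

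Macrophage genes at day 7 of the macrophage course went both ways, 9 higher and 5 lower of 29 (9 and 6 adjusted over the list alone), and the list did not pass (camera adjusted p = 0.944, adjusted p = 0.995 with an estimated correlation). Its median was 0.05 and its mean 0.18, the test pointed down, and after rescaling the median was -0.09 with 8 higher and 6 lower. Mertk, a receptor for apoptotic cells, rose by 1.3 ± 0.17, whereas the related receptor Axl fell by 1.05 ± 0.18. Among chemokines, Ccl17 and Ccl22, both on chromosome 8 (94810453 to 94812036 and 94745590 to 94751699, mm10), rose by 3.97 ± 0.36 and 3.05 ± 0.25 and Ccl12 by 4.21 ± 0.47, as did Ccr7, a receptor of lymph node homing (2.98 ± 0.27). F13a1 fell by 4.60 ± 0.58, F7 by 3.42 ± 0.27 and Asprv1 by 4.07 ± 0.35, and Cd34 rose by 1.32 ± 0.17. Oxidative phosphorylation genes rose in 26 of 39 cases and fell in 1 (30 and 1 adjusted over the list alone, camera adjusted p = 5.18e-06, adjusted p = 0.686 with an estimated correlation). Ndufb10 was at log2 0.75 ± 0.10. In all 4769 genes passed, 3274 higher and 1495 lower. After median-of-ratios scaling 2220 were higher and 2577 lower, and the median log2 of all genes went from 0.117 to -0.0118. After rescaling 32 interferon genes, 15 p53 targets, 12 lysosome and 18 oxidative phosphorylation genes were higher, and 31 mitotic, 19 histone, 14 granule and 15 glycolytic genes were lower. Taf8 fell by 0.34 ± 0.11 (limma adjusted p = 0.0155), a call lost without control replicate 2 (-0.33, adjusted p = 0.0532), control replicate 3 (-0.26, adjusted p = 0.0735) or knockout replicate 1 (-0.28, adjusted p = 0.0648) and with these groups fitted alone (adjusted p = 0.0522). Knockout replicates 2 and 3 held 4.14% and 4.66% of their TPM in Rpph1 and Rmrp, short structural RNAs, against 9.49% in replicate 1. Without both, which leaves 1 knockout library, Taf8, Cd177, Fcnb, Eno1 and Slc16a3 were at log2 -0.468, -1.837, -1.494, -0.758 and -1.043.

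At day 7 of the granulocyte course, mast cell, megakaryocyte and progenitor genes were higher in the knockout and monocyte, macrophage, granule and mitotic genes were lower. In the mast cell and basophil list 12 of 15 members rose, 12 adjusted over the list alone, with a median log2 of 1.75 (camera adjusted p = 0.000727, adjusted p = 0.69 with an estimated correlation). The tryptase Tpsb2 went from 22.6 ± 7.66 to 344 ± 216 TPM, the carboxypeptidase Cpa3 from 262 ± 66.6 to 2254 ± 1330 TPM, and Il1rl1, the IL-33 receptor, from 12.7 ± 4.73 to 106 ± 63.6 TPM. Megakaryocyte genes rose in 12 of 17 cases (16 adjusted over the list alone, camera adjusted p = 4.25e-05, adjusted p = 0.69 with an estimated correlation). The integrin Itga2b was at log2 2.12 ± 0.24 and Gp5 at 1.89 ± 0.22. Progenitor genes rose in 15 of 26 cases and 1 fell (16 and 2 adjusted over the list alone, camera adjusted p = 0.0155, adjusted p = 0.69 with an estimated correlation). Cd34 went from 14.9 ± 1.83 to 43.0 ± 5.44 TPM and Meis1 from 2.90 ± 0.837 to 15.6 ± 2.35 TPM, Gata2 rose by 1.76 ± 0.27 and Kit by 1.59 ± 0.32. Monocyte genes fell in 9 of 15 cases and rose in 3 (10 and 3 adjusted over the list alone, camera adjusted p = 4.25e-05, adjusted p = 0.135 with an estimated correlation). F13a1 went from 224 ± 83.0 to 5.60 ± 4.08 TPM, the monocyte antigen Ly6c2 from 1247 ± 131 to 183 ± 35.0 TPM, and the chemokine receptor Ccr2 from 110 ± 18.9 to 36.3 ± 8.07 TPM. Macrophage genes fell in 17 of 29 cases and rose in 3, the same adjusted over the list alone (camera adjusted p = 5.25e-08, adjusted p = 0.69 with an estimated correlation). Marco was at log2 -3.27 ± 0.14, Fcgr1 at -2.85 ± 0.29 and the fractalkine receptor Cx3cr1 at -2.08 ± 0.18.

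Some genes of both granule lists fell at day 7 granulocyte. Primary granule genes fell in 7 of 10 cases and 1 rose, the same adjusted over the list alone (camera adjusted p = 0.000272, adjusted p = 0.69 with an estimated correlation). Elane, neutrophil elastase, went from 312 ± 109 to 48.7 ± 52.2 TPM. Secondary and tertiary granule genes fell in 7 of 16 cases and 1 rose (9 and 2 adjusted over the list alone, camera adjusted p = 0.00017, adjusted p = 0.69 with an estimated correlation). Camp went from 1131 ± 545 to 28.0 ± 15.1 TPM. Saa3 went from 2125 ± 388 to 26.9 ± 10.5 TPM, Fcnb fell by 4.06 ± 0.49, Nkg7 by 3.73 ± 0.28, and Cybb, the catalytic subunit of the phagocyte oxidase, by 1.71 ± 0.27 (limma adjusted p = 5.35e-05). Mature neutrophil genes were 5 higher and 2 lower of 19, the same adjusted over the list alone, and the list did not pass (camera adjusted p = 0.89, adjusted p = 0.952 with an estimated correlation). Its median was 0.16 and its mean 0.23, the test pointed down, and after rescaling the median was -0.06 with 4 higher and 5 lower. The chemokine receptor Cxcr2 rose by 1.3 ± 0.14 and Csf3r, the G-CSF receptor, by 1.23 ± 0.16. Mitotic genes fell in 30 of 32 cases (32 adjusted over the list alone, camera adjusted p = 9.66e-16, adjusted p = 0.69 with an estimated correlation). Ube2c was at log2 -0.95 ± 0.16 and Ccnb1 at -0.81 ± 0.15. Of 25 p53 targets 18 rose and 1 fell, the same adjusted over the list alone (camera adjusted p = 0.000399, adjusted p = 0.69 with an estimated correlation). Ccng1 was at log2 1.5 ± 0.13, Phlda3 at 1.64 ± 0.19 and Cdkn1a at 1.77 ± 0.26. Interferon genes split, 8 higher and 8 lower of 36, the same adjusted over the list alone, without passing (camera adjusted p = 0.109, adjusted p = 0.811 with an estimated correlation), their median was -0.01 and their mean 0.03, and after rescaling 6 were higher and 13 lower. Myc and nucleolar genes rose in 23 of 29 cases, 23 adjusted over the list alone (camera adjusted p = 0.000147, adjusted p = 0.69 with an estimated correlation). Myc was at log2 0.98 ± 0.12. The chemokines Ccl6, Ccl2 and Ccl22 rose by 2.53 ± 0.19, 3.93 ± 0.22 and 4.61 ± 0.52, and Ccr7 by 4.40 ± 0.42.

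In all 5250 genes passed at day 7 of the granulocyte course, 3825 higher and 1425 lower. After median-of-ratios scaling 2429 were higher and 2937 lower, and the median log2 of all genes went from 0.165 to -0.0218. After rescaling 12 mast cell, 11 megakaryocyte, 14 progenitor, 17 p53 and 16 Myc and nucleolar genes were higher, and 9 monocyte, 18 macrophage, 7 primary granule, 9 secondary and tertiary granule and 32 mitotic genes were lower. Knockout replicates 2 and 3 held 2.29% and 2.34% of their TPM in Rpph1 and Rmrp against 7.00% in replicate 1. Without both, again with 1 knockout library left, Ube2c, Ccnb1 and Kit were at log2 -0.673, -0.561 and 0.908. Tpsb2, Cpa3, Il1rl1, Gata2 and Elane were at 2.13, 1.51, 1.36, 0.98 and -1.44.

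**Figure D2:**
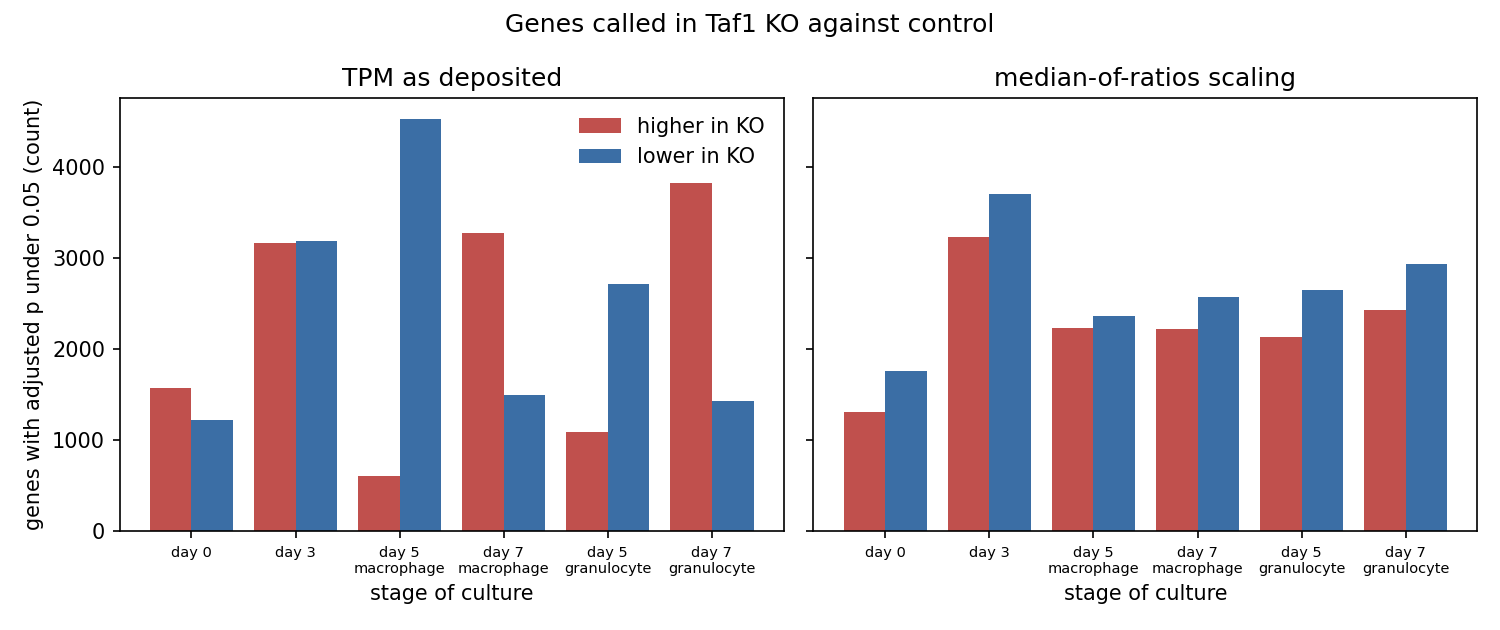
Number of genes past the limma adjusted p threshold of 0.05 (y axis) that were higher or lower in the knockout at the 6 stages (x axis), from TPM as deposited and after median-of-ratios scaling. At day 5 of the macrophage course the split was 611 higher and 4532 lower as deposited and 2237 higher and 2359 lower after scaling.

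**Figure D3:**
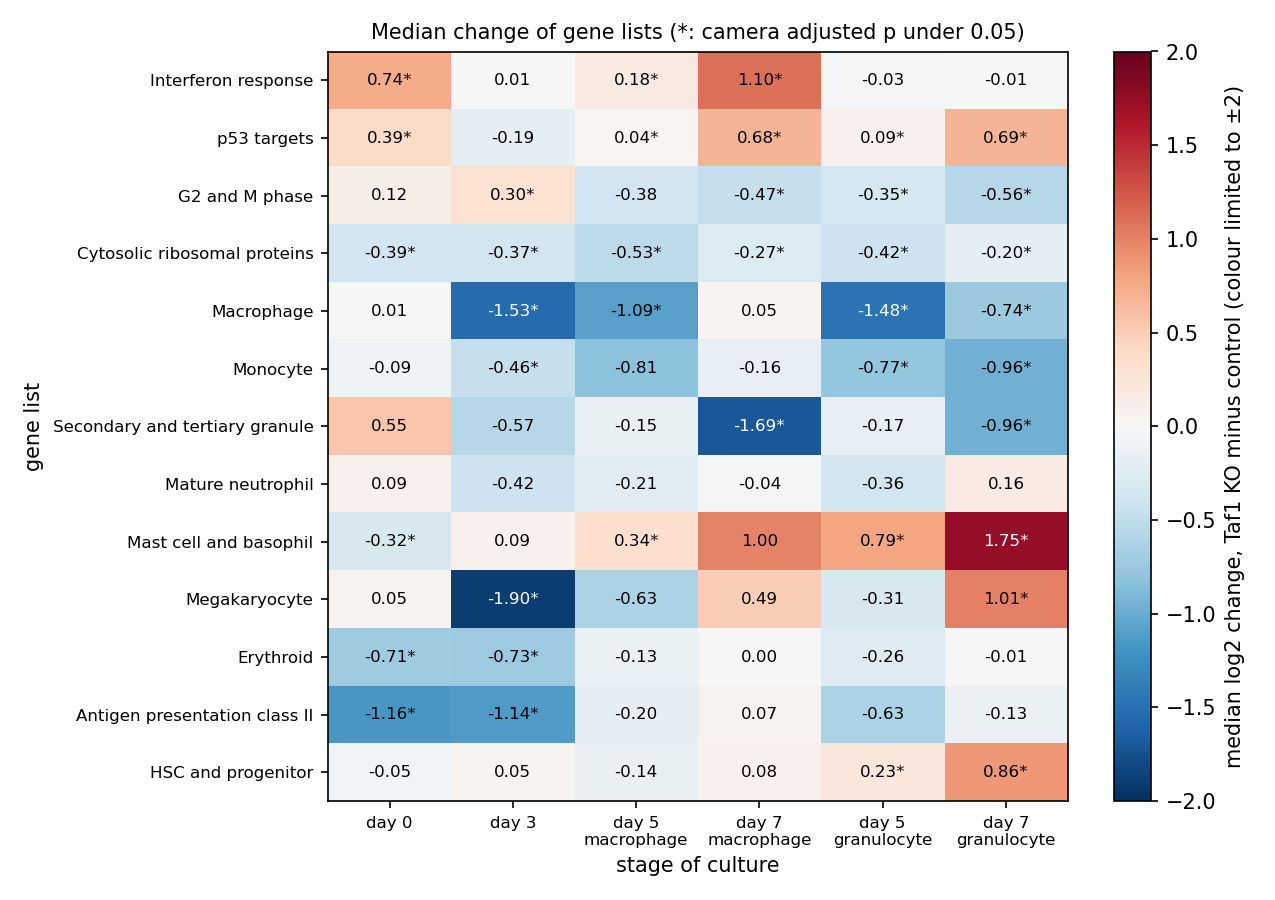
Median log2 difference between knockout and control over the tested members of 13 gene lists (y axis) at the 6 stages (x axis), as colour and printed value, with a star where camera passed; none passed with an estimated correlation. Medians ran from -1.90 (megakaryocyte, day 3) to 1.75 (mast cell and basophil, day 7 granulocyte), and after median-of-ratios scaling the sign turned for progenitor, secondary and tertiary granule and mature neutrophil genes at day 5 macrophage, progenitor, macrophage and class II genes at day 7 macrophage, interferon genes at day 5 granulocyte and mature neutrophil genes at day 7 granulocyte.

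The control courses showed what differentiation did without the knockout. By day 7 of the macrophage course Adgre1 had gone from 3.17 ± 0.384 to 292 ± 55.9 TPM, Gpnmb from 0.09 ± 0.0866 to 2591 ± 1060 TPM, and Lpl, lipoprotein lipase, from 0.497 ± 0.0777 to 689 ± 22.0 TPM. Ctsl rose by log2 6.57 ± 0.21 and the secreted phosphoprotein Spp1 by 10.1 ± 0.241, while Cd34, Kit and the carbonic anhydrase Car1 fell by 4.05 ± 0.17, 3.17 ± 0.18 and 8.90 ± 0.24 and the granule protease Ctsg by 4.31 ± 0.40. Macrophage genes rose in 26 of 29 cases and fell in 1, lysosome genes rose in 29 of 30 and fell in 1, and progenitor genes fell in 21 of 26 cases and rose in 2 (26 and 1, 29 and 1, and 22 and 2 adjusted over the list alone). These lists passed camera at adjusted p = 2.29e-13, 1.08e-13 and 1.16e-05, and stood at adjusted p = 0.162, 0.308 and 0.308 with an estimated correlation. By day 7 of the control granulocyte course Cxcr2 had gone from 2.59 ± 0.173 to 122 ± 8.15 TPM, the formyl peptide receptor Fpr1 from 0.0367 ± 0.0208 to 223 ± 11.3 TPM, and the collagenase Mmp8 from 1.01 ± 0.219 to 586 ± 81.7 TPM. Lcn2 rose by 7.54 ± 0.40, Saa3 by 10.5 ± 0.265 and Gpnmb by 10.4 ± 0.162, and Cd34 and Mpo fell by 3.71 ± 0.14 and 2.65 ± 0.36 (limma adjusted p = 2.35e-15 and 1.03e-06). Mature neutrophil genes rose in 18 of 19 cases, all 16 secondary and tertiary granule genes rose, macrophage genes rose in 28 of 29 with 1 lower, and progenitor genes fell in 18 of 26 with 2 higher, and these counts were the same adjusted over the list alone. Their camera adjusted p were 1.93e-13, 1.02e-08, 1.66e-16 and 0.00175, and their adjusted p = 0.0916, 0.221, 0.0916 and 0.485 with an estimated correlation. In the macrophage course 8781 genes passed (4022 higher and 4759 lower, 4581 and 4385 after rescaling). In the granulocyte course 9045 passed (3409 higher and 5636 lower, 4734 and 4445 after rescaling). There rescaling moved the median log2 of all genes from -0.243 to 0.0183. After rescaling the granulocyte lists had 19 neutrophil, 16 granule and 28 macrophage genes higher and 17 progenitor genes lower.

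Myeloid genes had risen and erythroid genes fallen by day 3, taken over both genotypes (6 libraries per day). Adgre1 rose by 4.02 ± 0.11, Gpnmb by 6.38 ± 0.18, Ccl6 by 7.90 ± 0.17, Cxcr2 by 4.46 ± 0.13, Mmp8 by 6.10 ± 0.27, and Arg1, arginase, by 10.1 ± 1.13. Car1 fell by 6.13 ± 0.17, the Rhesus antigen gene Rhd by 4.07 ± 0.16, Kit by 2.18 ± 0.13 and Mpo by 2.36 ± 0.30 (limma adjusted p = 4.8e-12 and 5.69e-07 for the last pair). Mature neutrophil genes rose in 18 of 19 cases, macrophage genes in 23 of 29 with 3 lower, and megakaryocyte genes in 15 of 17, while erythroid genes fell in 14 of 19 cases with 1 higher (18, 24 and 3, 15, and 14 and 1 adjusted over the list alone). Their camera adjusted p were 5.34e-10, 2.51e-09, 1.83e-06 and 0.000835, and their adjusted p = 0.182, 0.182, 0.381 and 0.463 with an estimated correlation. In all 9172 genes passed, 3878 higher and 5294 lower, or 4600 higher and 4739 lower after rescaling.

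The knockout courses turned on and off many of these genes. By day 7 of the knockout macrophage course Gpnmb went from 0.0833 ± 0.0252 to 5025 ± 1560 TPM, Spp1 from 3.80 ± 0.705 to 8518 ± 2690 TPM, and the fatty acid receptor Cd36 from 0.16 ± 0.06 to 1933 ± 88.8 TPM. Car1 fell by 9.0 ± 0.24 and Elane by 7.13 ± 0.56, while Cdkn1a and Mdm2 rose by 3.12 ± 0.18 and 2.59 ± 0.16 (limma adjusted p = 2.1e-12 and 5.32e-12). By day 7 of the knockout granulocyte course Gpnmb rose by 10.7 ± 0.162, the cystatin Stfa2, uncertain among its copies, by 12.4 ± 0.301, the death receptor Fas by 3.19 ± 0.19 and Phlda3 by 2.63 ± 0.19, while Elane fell by 6.75 ± 0.48 and Car1 was listed at 0 at day 7. In the macrophage course 8556 genes passed, 4211 higher and 4345 lower (3115 and 6435 with short structural RNA and histone genes left out). In the granulocyte course 8782 passed, 3732 higher and 5050 lower, or 4577 higher and 4563 lower after rescaling. There rescaling moved the median log2 of all genes from -0.145 to -0.00764.

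Whether genes activated in culture were activated less in the knockout was tested on genes that changed at least 2-fold from day 0 to day 7 on average over both genotypes. The 1958 activated genes of the macrophage course rose by a median log2 of 1.75 in controls and 1.79 in the knockout. The median of the interaction, the knockout change minus the control change, was 0.07 (quartiles -0.27 and 0.43, exact permutation p = 0.56, two-sided). Among 1807 activated genes of the granulocyte course the medians were 1.80 and 1.89 and that of the interaction 0.07 (quartiles -0.37 and 0.56, exact permutation p = 0.635). The 1283 repressed genes of the macrophage course fell by a median of 1.46 in controls and 1.35 in the knockout, with a median interaction of 0.13 (exact permutation p = 0.19). The 1773 repressed genes of the granulocyte course fell by 1.42 and 1.23, with a median interaction of 0.21 (exact permutation p = 0.065). Each test went through 400 assignments of genotype within day, the smallest p was 0.005, and shuffled assignments hold the genotype effect itself, which makes the test conservative. Of these genes, 24.1%, 32.6%, 19.3% and 24.3% had an interaction of their own past the threshold, in the order given. After rescaling the medians of activated genes turned to -0.02 and -0.10. Day 3 as the start gave 0.48 and 0.435 for activated genes of the macrophage and granulocyte courses (exact permutation p = 0.015 and 0.125) and 0.328 and 0.54 for repressed genes (exact permutation p = 0.23 and 0.015). With short structural RNA and histone genes left out the medians of repressed genes were -0.001 and 0.062 (exact permutation p = 1 and 0.415). Genes chosen on the controls alone gave -0.04 and -0.11 for activated and 0.27 (exact permutation p = 0.005) and 0.31 (p = 0.03) for repressed genes of the macrophage and granulocyte courses. Such a choice lets chance in the control values enter both the choice and the difference, which pushes the interaction against the control change, so these p-values can be too low. With genes chosen over both genotypes, the median for repressed genes of the granulocyte course passed without control replicate 3 at day 0 (0.24, exact permutation p = 0.03) or knockout replicate 1 at day 0 (0.24, p = 0.04).

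Gene by gene, the change from day 0 to day 7 of the macrophage course differed with genotype for 1409 genes, 841 with a larger and 568 with a smaller value in the knockout (943 and 964 after rescaling, 646 and 1171 with short structural RNA and histone genes left out). Dendritic cell genes had a more positive change in the knockout in 9 of 12 cases (11 adjusted over the list alone), with a median difference of 2.63 (camera adjusted p = 1.92e-11, adjusted p = 0.219 with an estimated correlation). Ccl17 differed by 4.51 ± 0.50, Ccl22 by 3.14 ± 0.35 and Ccr7 by 3.34 ± 0.38. In the class II list 7 of 10 members differed in that direction (8 adjusted over the list alone, camera adjusted p = 1.49e-06, adjusted p = 0.31 with an estimated correlation), including Cd74 at 4.33 ± 0.62 and H2-Aa at 3.70 ± 0.61, both lower at day 0. Secondary and tertiary granule genes had a more negative change in 13 of 16 cases and a more positive one in 1 (14 and 1 adjusted over the list alone, camera adjusted p = 1.17e-11, adjusted p = 0.298 with an estimated correlation). Camp differed by -6.33 ± 1.07 and Cd177 by -4.30 ± 0.75. Lcn2, S100a9 and Chil3 differed by -4.14 ± 0.64, -3.95 ± 0.72 and -3.71 ± 0.77, against knockout effects of 2.68, 3.02 and 4.67 at day 0. Mitotic genes had a more negative change in 16 of 32 cases (29 adjusted over the list alone, camera adjusted p = 1.13e-16, adjusted p = 0.349 with an estimated correlation), among them Ccna2 (-0.70 ± 0.14) and Birc5 (-0.81 ± 0.17). With day 3 as the start 4212 genes passed, Chil3 turned to 1.28, and Lcn2 (-1.41, adjusted p = 0.0929) and S100a9 (-1.56, adjusted p = 0.0982) did not pass. Without knockout replicates 2 and 3 at day 7, with 1 such library left, Chil3, Ccna2 and Birc5 were at -3.076, -0.587 and -0.722. Leaving out control replicate 2 at day 0, control replicate 1 or 2 or knockout replicate 3 at day 7 left 914, 909, 935 and 840 genes.

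In the granulocyte course the change differed with genotype for 2281 genes, 1475 with a larger and 806 with a smaller value in the knockout. After rescaling these were 1441 and 1661, and the median log2 of all genes went from 0.115 to -0.0166. With short structural RNA and histone genes left out they were 1155 and 1361. Mast cell and basophil genes had a more positive change in 13 of 15 cases (14 adjusted over the list alone, camera adjusted p = 6.99e-08, adjusted p = 0.401 with an estimated correlation). Tpsb2 was at log2 3.73 ± 0.53 and Il1rl1 at 3.49 ± 0.55. Megakaryocyte genes did so in 11 of 17 cases (13 adjusted over the list alone, camera adjusted p = 2.05e-06, adjusted p = 0.401 with an estimated correlation). Itga2b was at log2 2.82 ± 0.34. Progenitor genes did so in 12 of 26 cases (14 adjusted over the list alone, camera adjusted p = 0.000756, adjusted p = 0.401 with an estimated correlation). Meis1 was at log2 1.75 ± 0.26 and Cd34 at 1.26 ± 0.20. Interferon genes had a more negative change in 21 of 36 cases (24 adjusted over the list alone), with a median of -0.72 (camera adjusted p = 5.76e-16, adjusted p = 0.255 with an estimated correlation). Oasl2 differed by -1.92 ± 0.24 and Xaf1 by -1.27 ± 0.18. Mitotic genes had a more negative change in 22 of 32 cases (31 adjusted over the list alone, camera adjusted p = 7.13e-17, adjusted p = 0.401 with an estimated correlation). Bub1 was at log2 -1.15 ± 0.22. After rescaling 13 mast cell, 11 megakaryocyte and 13 progenitor genes had a more positive change, and 25 interferon and 31 mitotic genes a more negative one. Saa3 differed by -6.76 ± 0.38, Camp by -5.91 ± 0.91, Fcnb by -5.17 ± 0.69 and Elane by -4.01 ± 0.68, whereas Ccr7 and the granzyme Gzmb differed by 4.75 ± 0.60 and 4.61 ± 0.58 (limma adjusted p = 1.77e-05 and 1.74e-05). With day 3 as the start 4019 genes passed and Xaf1 did not (-0.41, adjusted p = 0.0921). Without knockout replicates 2 and 3 at day 7 Bub1 was at -0.878.

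Control cells at day 7 held less neutrophil, primary granule and mast cell RNA in the macrophage course than in the granulocyte course. Mature neutrophil genes were lower in the macrophage course in 15 of 19 cases, 15 adjusted over the list alone, with a median log2 of -1.70 (camera adjusted p = 1.64e-17, adjusted p = 0.0846 with an estimated correlation). Cxcr2 stood at 13.2 ± 3.87 TPM against 122 ± 8.15 TPM in the granulocyte course, Fpr1 at 34.6 ± 0.683 against 223 ± 11.3 TPM, and the cytokine Il1b at 2.79 ± 1.59 against 131 ± 28.7 TPM. Primary granule genes were lower in 9 of 10 cases, 9 adjusted over the list alone (camera adjusted p = 3.35e-08, adjusted p = 0.247 with an estimated correlation), and mast cell and basophil genes in 13 of 15, 13 adjusted over the list alone (camera adjusted p = 1.43e-10, adjusted p = 0.247 with an estimated correlation). The histidine decarboxylase Hdc was at log2 -3.25 ± 0.43 and Ms4a3 at -2.73 ± 0.43. Saa3 stood at 7.44 ± 2.14 against 2125 ± 388 TPM. S phase genes were higher in 28 of 32 cases, 28 adjusted over the list alone (camera adjusted p = 9.06e-07, adjusted p = 0.293 with an estimated correlation), as were the cyclins Ccnd1 (3.23 ± 0.13) and Ccne2 (0.81 ± 0.08), Cd36 (0.85 ± 0.10) and the chemokines Ccl2 and Ccl7 (3.55 ± 0.38 and 4.16 ± 0.53). Macrophage genes split, 9 higher and 6 lower of 29 (9 and 7 adjusted over the list alone), with Marco at -2.11 ± 0.20. That list did not pass (camera adjusted p = 0.0876, adjusted p = 0.698 with an estimated correlation), its median was 0.19 and its mean -0.13, the test pointed down, and after rescaling the median was -0.03 with 6 higher and 8 lower. It passed with short structural RNA and histone genes left out (adjusted p = 0.043). In all 5257 genes passed, 4095 higher and 1162 lower. After rescaling 2244 were higher and 2198 lower, and the median log2 of all genes went from 0.209 to 0.0175. Rescaling left 15 neutrophil, 9 primary granule and 13 mast cell genes lower and 16 S phase genes higher.

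The knockout effect at day 7 differed between the courses for 367 genes, 186 with a higher value in the macrophage course and 181 with a lower one (limma). With the replicate number as a block, pooled over genotypes, 700 passed. Interferon genes had the higher value in 21 of 35 cases (29 adjusted over the list alone), with a median difference of log2 1.23 (camera adjusted p = 5.49e-34, adjusted p = 0.181 with an estimated correlation). Ifit3 differed by 3.74 ± 0.50, Ifit1 by 3.19 ± 0.36 and Rsad2 by 3.28 ± 0.31. Macrophage genes had the higher value in 7 of 29 cases (13 adjusted over the list alone, camera adjusted p = 5.64e-13, adjusted p = 0.181 with an estimated correlation). Marco was at log2 2.78 ± 0.29, Fcgr1 at 2.78 ± 0.47 and Apoe at 3.85 ± 0.56. Saa3 differed by 6.81 ± 0.46 and Lrg1, a secreted glycoprotein of neutrophils, by -3.03 ± 0.52 (limma adjusted p = 7.63e-05 and 0.0125). The count was 667 after rescaling, 227 with the stricter filter of 5 TPM, 580 with short structural RNA and histone genes left out, and 13 without knockout replicates 2 and 3. With 1 knockout library per lineage left, Ifit1, Ifit3, Marco, Fcgr1 and Lrg1 were at 2.789, 3.16, 2.908, 2.238 and -2.527. Leaving out macrophage control replicate 1, 2 or 3 gave 131, 124 and 585, granulocyte control replicate 1 or 2 gave 173 and 108, macrophage knockout replicate 2 or 3 gave 122 and 161, and granulocyte knockout replicate 1, 2 or 3 gave 959, 136 and 133.

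**Figure D4:**
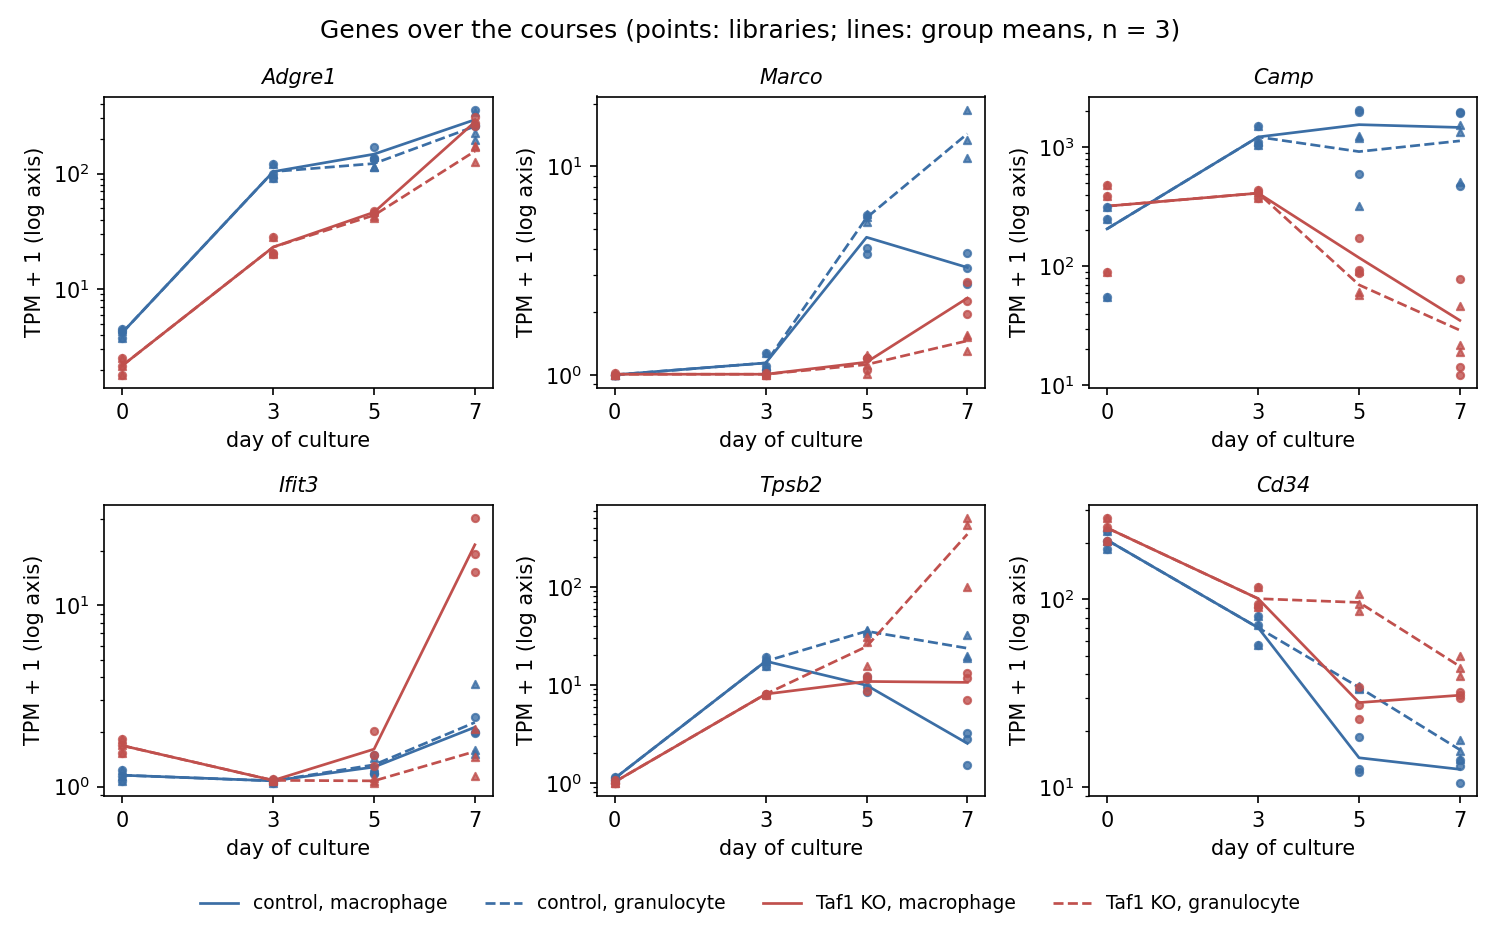
Level of Adgre1, Marco, Camp, Ifit3, Tpsb2 and Cd34 as TPM + 1 on a log axis (y axis) at days 0, 3, 5 and 7 (x axis) of both courses in control and knockout cells, with 1 point per library and lines through the means of n = 3; the day 0 and day 3 libraries are the same in both courses. At day 7 Ifit3 was at 20.6 TPM in knockout and 1.13 TPM in control macrophage cultures, and Tpsb2 at 344 TPM in knockout and 22.6 TPM in control granulocyte cultures.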

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

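In this part the tests of the mast cell pattern and the exchange of whole cultures were chosen only after the result was seen, and the tests of each difference and the other regroupings of libraries were planned.

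Each result here is a difference between knockout effects that was tested as such. The knockout effect at day 7 differed between the courses for 367 genes (limma), and 6 of 100 splits of the same libraries gave as many, so chance was not excluded, and the highest other split gave 6657. That is several times the real count and points to a structure of the samples: in all 5 of the other splits as large, genotype labels were mostly opposite in the macrophage and granulocyte parts, so these splits hold the knockout effect itself. The 100 splits exchanged labels in each lineage apart, although the protocol divides each culture between the lineages. With libraries of the same genotype and number taken as 1 culture and exchanged together, the highest other split gave 2 genes, and with 10 such splits a share under 0.05 is out of reach. The change from day 0 to day 7 differed with genotype for 1409 genes in the macrophage course, where 6 of 100 splits gave as many and the highest other gave 3718. In the granulocyte course it differed for 2281 genes, where 8 of 100 splits gave as many and the highest other gave 3939. Chance was not excluded for either, and in all 5 and all 7 of the other splits as large the genotype labels were mostly opposite between the days.

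Among named results, the interferon list median was 1.23 for the lineage difference at day 7. It was -0.72 for the granulocyte interaction, with the list higher in the knockout at day 0. Ifit3 differed by 3.74 and Saa3 by 6.81 between the courses at day 7. In the macrophage course the interaction was 4.33 for Cd74, which was lower in the knockout at day 0 (log2 -2.97), and -6.33 for Camp. In the granulocyte course it was 3.73 for Tpsb2 and -6.76 for Saa3.

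Mast cell and progenitor genes were higher in the knockout at day 7 of the granulocyte course, with list medians of 1.75 and 0.86, and the Tpsb2 interaction goes with this. A lower share of the main cell type stays open, since that type may include macrophages, whose genes rose in the control course. Monocyte, macrophage and eosinophil medians were -0.96, -0.75 and -0.81, and megakaryocyte and dendritic medians 1.01 and 0.3. A different share of short structural RNA and histone genes is argued against as the whole cause, since the lower quartile of the mast cell and progenitor lists together was 0.17, and their median 1.02, once they were left out. Knockout replicates 2 and 3 held less Rpph1 and Rmrp than replicate 1, and without them Tpsb2, Cpa3 and Kit were at 2.13, 1.51 and 0.908. A difference in their preparation stays open, since 1 knockout library would remain. More mast cells and progenitors in the culture, or more of these transcripts per cell, both stay open, since bulk RNA does not separate them. Counts of sorted cells would tell them apart.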

How the results depend on the processing

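In this part leaving out short structural RNA and histone genes, subtracting the median of all genes and leaving out knockout replicates 2 and 3 at day 7 were chosen only after the result was seen. Of 5186 alternative values of 287 gene results, apart from Taf1 at the 6 stages, 5142 kept their direction and side of the threshold, 39 lost their call and 5 turned: Mpo at day 0 (0.07) was -0.012 after median-of-ratios scaling, -0.075 without control replicate 2 and -0.01 without knockout replicate 2, Kit at day 0 (-0.06) was 0.023 without control replicate 1 and at lowest -0.163, and the Chil3 interaction of the macrophage course (-3.71) was 1.28 with day 3 as the start. Taf1 at day 3 (-0.17) passed after median-of-ratios scaling (-0.21) and with short RNA and histone genes left out (-0.20). Without knockout replicates 2 and 3 the counts at day 7 were 1298 for the macrophage course (4769), 1583 for the granulocyte course (5250), 355 and 755 for the interactions (1409 and 2281) and 13 for the knockout effect between lineages (367); 1 knockout library per lineage remains there, and the spread comes from the other groups. With the groups fitted alone 3806 became 2493 at day 5 granulocyte. Day 3 as the start gave 4212 and 4019 for the interactions. The knockout effect between lineages was 227 with the 5 TPM filter, which tests fewer genes, 667 after median-of-ratios scaling and 580 with short RNA and histone genes left out. Leaving out these genes also moved the numbers higher and lower, to 2199 and 2055 at day 7 macrophage, 2870 and 1860 at day 7 granulocyte, 3538 and 5879 and 2914 and 6741 in the control courses, 2724 and 6964 in the knockout granulocyte course, 3331 and 6430 for day 3 against day 0 and 240 and 340 for the knockout effect between lineages. With the replicate number as a block, where the pairing holds between lineages, it was 700, and the block changed no other call of a comparison and, among genes, that of S100a8 at day 5 granulocyte (adjusted p = 0.054). Apart from the correlations at day 5 macrophage and between lineages, the samples share only a number.

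The median interaction of activated genes (0.07 in each course) was -0.023 and -0.10 after median-of-ratios scaling, -0.039 and -0.11 with genes chosen on controls, -0.062 and -0.061 with short RNA and histone genes left out, and -0.086 and -0.14 without knockout replicates 2 and 3 in the macrophage and granulocyte courses and it was 0.48 and 0.435 from day 3. For repressed genes of the macrophage course (0.13) it was 0.27 with genes chosen on controls, 0.328 from day 3, 0.089 after median-of-ratios scaling and -0.001 with short RNA and histone genes left out. For those of the granulocyte course (0.21) it was 0.31, 0.54, 0.151 and 0.062 in the same order. A choice on controls alone pushes the interaction against the control change, since chance in the control values enters both. List tests, 230 of 485, fell to 0 with an estimated correlation. Lists that did not pass turned direction: macrophage at day 7 macrophage (adjusted p = 0.944) with fry (0.19), median-of-ratios scaling (0.805) and short RNA and histone genes left out (0.83), mature neutrophil at day 7 granulocyte (0.89) likewise (0.0651, 0.727 and 0.903), and with fry interferon at day 7 granulocyte (0.93) and macrophage between control lineages (0.769). Fry also cost the calls of mast cell genes at day 0 (0.0739) and of interferon and oxidative phosphorylation genes at day 5 macrophage (0.162 and 0.797), and mature neutrophil genes at day 5 granulocyte gained theirs (0.00629). Except where a reason is given, the cause was not tested.

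Leaving out 1 library at a time changed these: Taf1 at day 3 (-0.24 to -0.12, passing without control replicate 1 or knockout replicate 2), the interaction of the macrophage course (840 to 2039, moved by over 1.5 times without control replicate 2 at day 0 at 914, control replicates 1 and 2 at day 7 at 909 and 935 and knockout replicate 3 at day 7 at 840), the knockout effect between lineages (108 to 959, by 10 of 12 libraries) and repressed genes of the granulocyte course (0.16 to 0.26, with exact permutation p = 0.03 without control replicate 3 and p = 0.04 without knockout replicate 1 at day 0). The medians that did not pass moved as well without changing side of the threshold: activated genes to between 0.023 and 0.157 in the macrophage course and between 0.008 and 0.18 in the granulocyte course, and repressed genes of the macrophage course to between 0.085 and 0.161. The counts of the 6 stages, the time courses, the averages and the control lineages stayed within 1.5 times and the other Taf1 values kept their calls. Depth is unknown for TPM, so what it limits was not computed; the self-test recovered few changes of 0.5 log2 in the interactions.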

Other observations

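In this part the tests of the day 0 and day 5 patterns were chosen only after the result was seen, except leaving out S100a8 and S100a9, and the genes singled out in the next paragraph were chosen after their values were seen.

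Of 11826 genes tested at all 6 stages, 198 were higher and 208 lower in the knockout at every stage by limma, against 0.171 and 0.411 if calls at the stages were independent, which parts of common cultures need not be, and 286 and 388 after median-of-ratios scaling. Of these, 158 and 202 held in both. The steadiest named rises included Hexim1 (log2 1.07 to 1.24 over the stages), Kank3 (1.31 to 1.62), Endog, a mitochondrial nuclease (1.05 to 1.39), and Cirbp, a cold-inducible RNA-binding protein (0.91 to 1.62). Irf7 ranged from 0.59 to 2.81 and Rpl26 from 0.61 to 2.15. Lower at every stage were Nkg7 (-3.76 to -1.55), Epx (-3.45 to -1.55), Lmo1 (-2.89 to -1.72) and Cercam (-2.21 to -1.71). Between the courses at day 5, 467 genes were higher and 2366 lower in both, against 55.2 and 1020 if independent, and 11 were opposite. After median-of-ratios scaling these were 1431, 1712 and 20.

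Other parts of the transcription and translation machinery also moved in the average over each course. RNA polymerase II subunits rose in 9 of 12 cases in the macrophage course and 10 in the granulocyte course, the same adjusted over the list alone (camera adjusted p = 0.000146 and 0.000566, adjusted p = 0.596 and 0.563 with an estimated correlation), and its general factors other than TFIID rose in 11 and 12 of 16 cases, the same adjusted over the list alone (camera adjusted p = 0.000491 and 0.00123, adjusted p = 0.596 and 0.785 with an estimated correlation). Cytosolic ribosomal protein genes fell in 58 of 65 cases and rose in 1 in each course (58 and 60 lower adjusted over the list alone), with medians of -0.36 and -0.31 (camera adjusted p = 1.17e-14 and 6.03e-18, adjusted p = 0.596 and 0.646 with an estimated correlation). Oxidative phosphorylation genes rose in 30 and 29 of 39 cases and fell in 1 in each, the same adjusted over the list alone (camera adjusted p = 1.73e-07 and 1.63e-05, adjusted p = 0.596 and 0.785 with an estimated correlation). Cholesterol synthesis genes, 20 of 21 higher at day 3, were 1 higher and 5 lower at day 7 of both courses (1 and 2, and 1 and 5, adjusted over the list alone), or 1 and 10 after rescaling (camera adjusted p = 0.00233 and 0.00179, adjusted p = 0.77 and 0.746 with an estimated correlation).

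S100a8, S100a9, Chil3, Lcn2 and interferon genes were higher in the knockout at day 0. Mature neutrophils carried over would raise their other abundant transcripts as far, but the upper quartile of the 17 other tested members of the neutrophil list was 0.33 against a lower bound of 2.04 for S100a8. Of these, Slpi (99.9 to 253.4 TPM, log2 1.33) and Wfdc21 (110 to 225.7 TPM, 1.09) passed, also under that bound, and Mmp8 stood at 1.01 and 0.947 TPM. Library scaling is argued against for the interferon genes, since their median was 0.67 after it. Maturing neutrophil precursors stay open, since Ltf (10.1 to 44.6 TPM, log2 1.81 ± 0.82) and Ngp (63.5 to 195 TPM, 1.56 ± 0.75) were higher without passing (limma adjusted p = 0.116 and 0.143). How the deletion was induced is not given in the sources used here, so an interferon response to the inducing agent was not tested, nor was the Taf1 knockout itself as the source.

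At day 5 of the macrophage course 11.9% of passing genes were higher in the knockout. Median-of-ratios scaling gave 48.7%, but it centres the ratios, so a scaling effect and a true excess of falls cannot be told apart by it. Short structural RNA and histone genes are argued against, since leaving them out gave 10.2%. A larger share of S100a8 and S100a9 in the knockout may account for part of it: without both, 33% of 4020 passing genes were higher and the median of all genes was -0.08 rather than -0.23. The rest stays open, since TPM holds no absolute amount of RNA per cell.

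For other comparisons the real split of the libraries gave the highest count, 1 of the splits made. With 10 splits a share under 0.05 is out of reach, and the real count and the highest other were 2790 and 5 at day 0, 6355 and 0 at day 3, 5143 and 0 at day 5 macrophage, 3806 and 2 at day 5 granulocyte, 4769 and 1473 at day 7 macrophage, and 5250 and 2418 at day 7 granulocyte. If equal numbers at day 5 macrophage are taken as pairs, the highest other among the 4 splits that part every pair was 0. The same holds of day 7 against day 0, with 8781 and 0 (control) and 8556 and 1 (knockout) in the macrophage course and 9045 and 0 and 8782 and 0 in the granulocyte course, and of the control lineages with 5257 and 1. With 100 splits day 3 against day 0 gave 9172 and 7631. The average effects gave 7209 and 2946 (macrophage) and 7030 and 3436 (granulocyte). Chance was not excluded here, since libraries split apart may share cultures.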
